A study of Mus musculus with 12 samples.

How the data were processed

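RNA from whole bladders of FVB/N mice at postnatal day 1 was measured on 12 one-colour Affymetrix whole-genome mouse arrays. Per the labels, total RNA was purified on RNeasy columns, amplified in 1 round, labelled with biotin and not pooled, and every animal was male. Each array therefore stands for 1 sample, and the spread between the arrays of a group is the spread used in every test. The groups were SMGA/EGFP (3 arrays), in which the smooth muscle gamma actin (Actg2) promoter drove a green fluorescent protein, SMAA/EYFP (3 arrays), in which the smooth muscle alpha actin (Acta2) promoter drove a yellow fluorescent protein, and wild type (6 arrays). FVB/N females were mated to transgenic males for the transgenic litters, so litter, sire and genotype cannot be told apart.

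The deposited values are linear intensity per probe set, made by the authors with GCOS per the labels, which give no version. The algorithm, detection calls and filters behind them are not stated. The mean over the probe sets between the 2nd and 98th percentile lay between 1499.55 and 1499.59 on all 12 arrays, so each array had been scaled by a single factor, while median intensity ran from 229.39 to 305.94. Of the values on an array, 8.33% to 10.5% lay below the pseudocount. For arrays, their number limits the precision: there were 3, 3 and 6 per group.

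From the 45101 probe sets, 64 controls were left out of the tests. Values were converted as log2(intensity + 16) and quantile-normalized between arrays. The 22518 probe sets whose mean over the 12 arrays lay above the median of all means (log2 8.02) were tested. Gene symbols came from GEO's platform annotation, updated by Entrez number through a RefSeq gene table of assembly GRCm38.p6, which was used for names and neighbours only; the update changed 0 symbols. Of the 45037 probe sets other than controls, 34945 had 1 symbol, 932 had several and 9160 were not listed. Of those tested, 20089 had 1 symbol and covered 11730 genes. No gene was named from a probe set with several symbols.

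Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with all 12 arrays in the fit so that the 3 groups shared 1 estimate of the spread, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were SMGA/EGFP against wild type, SMAA/EYFP against wild type, SMGA/EGFP against SMAA/EYFP, and the mean of both transgenic groups against wild type. Errors of log2 differences are limma's moderated standard errors (SE), and errors of group levels are standard deviations (SD). Single values of the promoter genes and of the ratios of 3-prime over 5-prime control probe sets were compared by exact permutation tests, two-sided, of the difference of means. With 3 arrays against 3, an exact permutation test cannot go below p = 0.10.

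The named genes followed a rule. In each comparison these were the genes past the threshold whose arrays did not overlap between the groups. The rule took up to the 12 largest rises and the 12 largest falls. Slc39a8 and Atp10d lay beyond the 12 largest falls in SMGA/EGFP against SMAA/EYFP and are named there as well. Where fewer than 10 genes passed, the genes of smallest p up to 10 were added and are given as not passing. Acta2, Actg2, Xist and the Y-linked genes were named in any case, as were up to 4 members of smallest p per gene list. The probe set of highest mean stood for a gene of a list. The design, the rule, the lists and the alternatives below, except where stated, were fixed before the data were examined.

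The 25 gene lists were smooth muscle contractile apparatus, smooth muscle receptors and ion channels, urothelium, fibroblasts and extracellular matrix, endothelium, pericytes, mesothelium, erythroid cells, macrophages and other leukocytes, mast cells, neurons and Schwann cells, skeletal muscle, adipocytes, prostate and Wolffian duct, cell cycle, endoplasmic reticulum stress, cytosolic heat shock, immediate early genes, interferon response, oxidative phosphorylation, cytosolic ribosomal proteins, hypoxia and glycolysis, circadian clock, glucocorticoid and fasting response, and Hedgehog, Wnt and BMP signalling. They held 483 distinct genes, of which 388 were tested and 40 had no named probe set. Lists were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene and Benjamini-Hochberg adjustment over the 24 testable lists of a comparison. Camera with an estimated correlation and fry, which asks whether the members move one way and makes no comparison with other genes, were alternatives. A list score is the mean log2 deviation of the members from their means over the 12 arrays.

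Alternatives were values as deposited without further normalization, arrays centred on their median, pseudocounts of 1 and 64, no filter and filters at the 25th and 75th percentiles, 1 probe set per gene, eBayes without a trend or with the robust option, array weights, only the arrays of the groups compared, a fold of at least 1.5 beside the adjusted p, and each array left out in turn. The database record numbers fall into 2 consecutive runs of 6 arrays: the first run holds SMGA/EGFP 1 to 3 with wild type 1 to 3, and the second run holds SMAA/EYFP 1 to 3 with wild type 4 to 6. The labels do not call these runs a batch. The run entered as a block in an alternative chosen beforehand, and fits to the arrays of 1 run alone were chosen after seeing the data.

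The probe set test was tested on simulated data drawn from the real means and spreads, with 200 changed probe sets among 22518 in each of 10 draws. In SMGA/EGFP against wild type, 32.8% of changes of 1.5-fold, 77.2% of changes of 2-fold and 98.8% of changes of 4-fold were recovered. In SMAA/EYFP against wild type these shares were 35.5%, 76.3% and 98.0%, and in SMGA/EGFP against SMAA/EYFP 20.3%, 64.8% and 96.8%. For both transgenic groups against wild type they were 53.7%, 87.0% and 98.9%. False calls made up 4.50% to 5.93% of the calls. In 10 simulated draws over 11730 genes for SMGA/EGFP against wild type, a changed list was found 10 times and 1 other list was called. In all these draws the genes varied independently and the runs of record numbers did not differ. Other splits of the real arrays of this comparison called a median of 6 lists, so these rates need not hold for the real data. In 10 draws of random p over 11704 genes, 13 genes in a window of 25 neighbours were given a small p. The fullest window overlapped the changed one 10 times, which shows only that the scan locates such a window. The test by permuted gene order, the list test in the other comparisons, fry and the exact permutation tests were not simulated.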

Results

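The series asked how expression of a smooth muscle transgene affects the expression profile of the newborn mouse bladder. Whole bladders were profiled at postnatal day 1 on 12 arrays: 3 from mice with EGFP under the Actg2 promoter (SMGA/EGFP), 3 from mice with EYFP under the Acta2 promoter (SMAA/EYFP) and 6 from wild-type mice. Median intensity per array lay between 229.39 and 305.94. Across probe sets, the correlation between arrays of a group was 0.956 to 0.984 (median 0.974) and that between arrays of different groups was 0.948 to 0.986 (median 0.972), so these correlations did not separate the groups. On the first principal component, with 31.2% of the variance, the SMGA/EGFP arrays lay at -36.7 to -11.6 and the SMAA/EYFP arrays at 3.44 to 31.7. This followed the runs of database record numbers, since the 6 arrays of the second run were positive and 5 of 6 of the first run were negative, wild type included. Genes are not independent replicates in such a correlation.

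No difference between the groups was detected in the actin genes whose promoters drove the transgenes, but their main probe sets were near the top of the intensity range. Acta2, smooth muscle alpha actin, measured log2 15.95 ± 0.06 (SD, n = 6) in wild type, 15.93 ± 0.05 (SD, n = 3) in SMGA/EGFP and 15.93 ± 0.11 (SD, n = 3) in SMAA/EYFP. Actg2, smooth muscle gamma actin, measured 15.82 ± 0.02 in wild type, 15.83 ± 0.03 in SMGA/EGFP and 15.82 ± 0.02 in SMAA/EYFP. Exact permutation tests (two-sided) of the differences from wild type gave p = 0.690 and 0.738 for Acta2 and p = 0.619 and 0.976 for Actg2, in SMGA/EGFP and SMAA/EYFP in turn. Between the transgenic groups, the exact test gave p = 1.00 for Acta2 and p = 0.600 for Actg2, where 3 arrays against 3 cannot go below 0.10. By mean level these probe sets ranked 7 and 29 on the array, where differences are compressed, so equal levels are not shown. The 2 dimmer Acta2 probe sets differed from wild type by 0.01 ± 0.32 and 0.04 ± 0.31 (SE) in SMGA/EGFP and by 0.22 ± 0.32 and 0.15 ± 0.31 in SMAA/EYFP, too imprecise to show equality. Over the smooth muscle contractile apparatus list, 0 of 31 genes passed in any comparison and the median log2 difference was -0.02 in SMGA/EGFP and -0.03 in SMAA/EYFP (camera, adjusted p = 0.650 and 0.0919). With the run of record numbers as a block, its mean in SMAA/EYFP was -0.15 (adjusted p = 0.00108 at the preset correlation), against -0.07, and it was -0.15 (0.000718) against the wild-type arrays of the same run. Its members of smallest p were Ldb3, a protein of muscle Z-discs, at -0.48 ± 0.24 (SE) in SMGA/EGFP (limma adjusted p = 0.724) and Myocd, the coactivator of smooth muscle genes, at -0.35 ± 0.15 in SMAA/EYFP (limma adjusted p = 0.991).

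No difference in RNA quality between the groups was detected by the ratios of control probe sets, which does not show equality. The log2 ratio of 3-prime over 5-prime Gapdh probe sets differed from wild type by 0.01 in SMGA/EGFP and -0.08 in SMAA/EYFP (exact permutation test, two-sided, p = 0.786 and 0.214). For Actb the differences were 0.02 and 0.01 (p = 0.881 for each, by the same exact test). Between the transgenic groups, the Gapdh ratio differed by 0.10 (exact permutation test, two-sided, p = 0.20, with 0.10 the smallest possible). The Actb ratio differed there by 0.0017.

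All animals were male per the labels, and 1 array did not show a male profile. Wild type 4 had an Xist intensity of 29604, against 80.1 to 250 in the other 11 arrays. Xist is the RNA that silences an X chromosome in female cells. The Y-linked genes were near background on that array: Eif2s3y at 26.7 against 3284 to 5096, Kdm5d at 28.0 against 938 to 1465, and Uty at 48.6 against 724.5 to 1199. Ddx3y had no named probe set. The fits below keep this array, and the counts without it stand beside each comparison where they differ by more than 1.5 times.

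**Figure D1:**
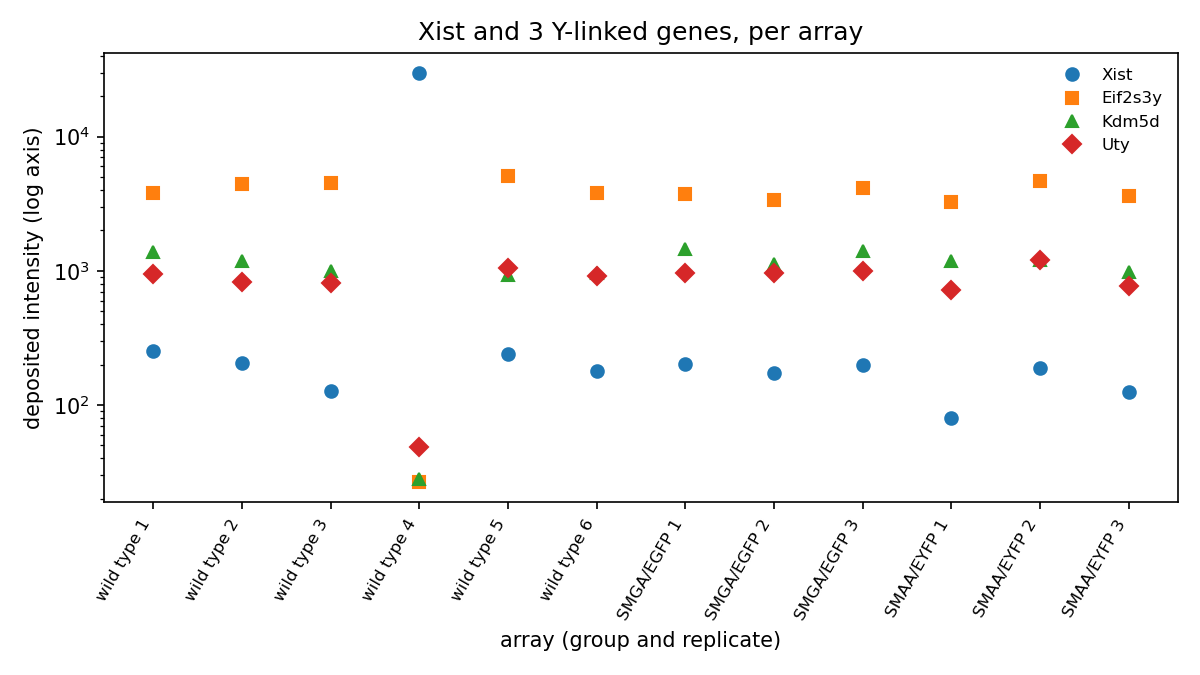
Deposited intensity (log axis) of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty in each of the 12 arrays, 1 symbol per gene and array. Wild type 4 has Xist at 29604 and Eif2s3y at 26.7, while the other 11 arrays have Xist at no more than 250 and Eif2s3y at 3284 or more.

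SMGA/EGFP against wild type asked what the Actg2-driven transgene changed, and the genes that fell included 3 of the mesothelium list. Mesothelium is the cell layer that covers the outside of the bladder. Gpm6a, a membrane glycoprotein, fell by 2.74 ± 0.34 on the log2 scale (SE, n = 3 and 6; adjusted p = 0.00557), from 10.57 ± 0.64 (SD) to 7.83 ± 0.30. Lrrn4, a leucine-rich repeat membrane protein, fell by 2.75 ± 0.36 (adjusted p = 0.00946), and Muc16, the mucin that carries the CA125 antigen, fell by 2.06 ± 0.30 (adjusted p = 0.0167). All 6 tested genes of the mesothelium list were lower, with a median log2 difference of -1.74. Over all genes 3 members passed, and 4 passed adjusted over the list alone, the fourth being Msln (mesothelin) at -1.41 ± 0.30. Wt1, a transcription factor of mesothelial cells, was at -0.47 ± 0.28, and Upk3b, a uroplakin that mesothelium also makes, was at -0.13 ± 0.10; neither passed, Wt1 was at -0.17 without SMGA/EGFP 2, and both were named after their values were seen. Camera gave the list an adjusted p = 1.10e-09, against adjusted p = 0.143 with an estimated correlation and 0.00843 with fry. The exact permutation test of the list score (two-sided) gave p = 0.0119, the smallest that 3 arrays against 6 allow. Within the first run of record numbers, the list's mean difference was -1.25 (camera adjusted p = 2.00e-10), against -1.59 over all arrays.

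**Figure D2:**
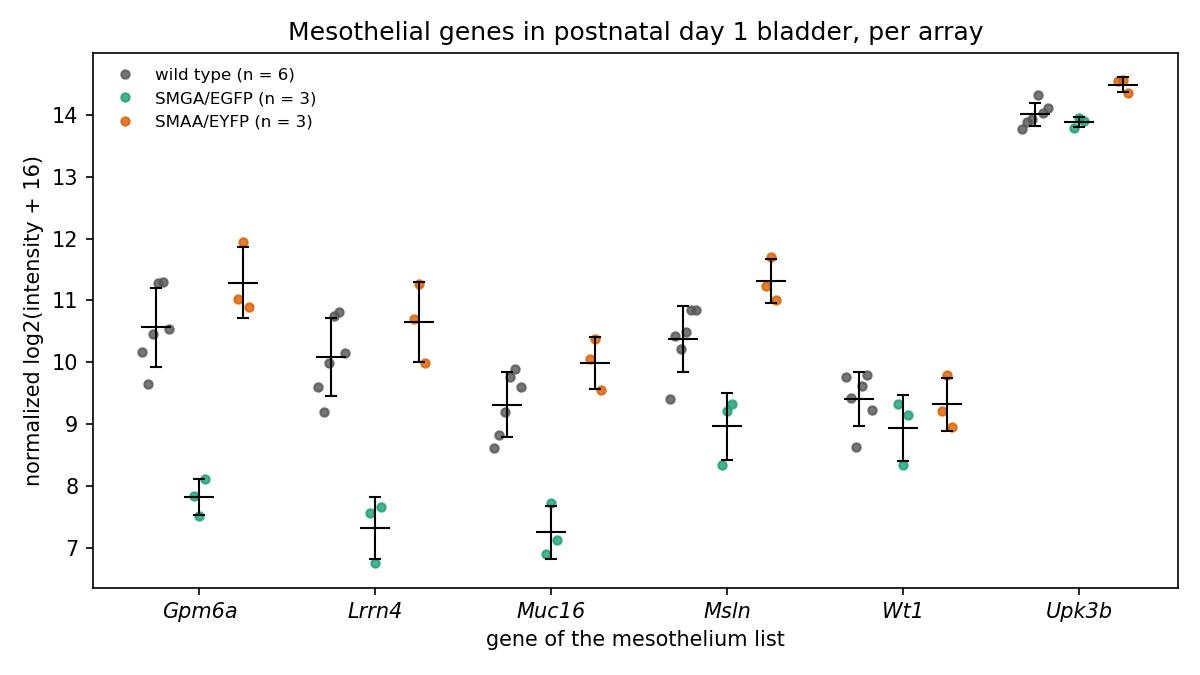
Normalized log2(intensity + 16) of the 6 tested mesothelium genes in each array (dots) of wild type (n = 6), SMGA/EGFP (n = 3) and SMAA/EYFP (n = 3), with the group mean and SD as bars. Gpm6a, Lrrn4, Muc16 and Msln are lower in each SMGA/EGFP array than in any array of the other groups, while Upk3b overlaps, at 13.79 to 13.95 in SMGA/EGFP and 13.78 to 14.32 in wild type.

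Other genes, not on the mesothelium list, fell with them in SMGA/EGFP. Whether mesothelial cells express these genes too was not tested. Bst1, a cell surface enzyme that makes cyclic ADP-ribose, fell by 3.31 ± 0.35 (adjusted p = 0.00151) to a level near background, 5.38 ± 0.82 (SD), so its fold is uncertain. Fgfbp1, a carrier protein that releases fibroblast growth factors, fell by 2.43 ± 0.22 (adjusted p = 0.000469). Bnc1, a zinc finger protein of epithelial and germ cells, fell by 2.31 ± 0.35 (adjusted p = 0.0244), and Smpd3, a neutral sphingomyelinase, fell by 1.45 ± 0.18 (adjusted p = 0.00557). Nsfl1c, a cofactor of the p97 ATPase, fell by 0.90 ± 0.13. For Atp6ap2, the prorenin receptor and an accessory subunit of the vacuolar ATPase, 1 probe set fell by 1.33 ± 0.08 (adjusted p = 4.91e-06), while the gene's other probe sets were at 0.05 and -0.03. Pnisr, a nuclear protein rich in serine and arginine, likewise had 1 probe set that fell by 0.85 ± 0.10 (adjusted p = 0.00516) and 6 others between -0.28 and 0.20. The rises were Sowahb (1.22 ± 0.18, adjusted p = 0.0167) and Tcl1b3 (0.97 ± 0.16, adjusted p = 0.0390). In each of these 12 genes the SMGA/EGFP arrays did not overlap with the wild-type arrays.

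In total, 14 of 22518 probe sets passed in SMGA/EGFP against wild type, 2 higher and 12 lower, for 12 genes and 1 probe set without a listed gene (-2.49 ± 0.35); 1559 had an unadjusted p under 0.05, against 1125.9 by chance. The count was 9 without SMGA/EGFP 1, wild type 3, wild type 4 or wild type 6, and 6 without SMGA/EGFP 2. It was 8 with only the arrays of the groups compared, 10 with the run of record numbers as a block and 1 within the first run, where 3 arrays met 3 and Atp6ap2 passed. Atp6ap2, Fgfbp1, Pnisr and Smpd3 passed without each of the 12 arrays in turn, and Bst1 in the 5 of these fits in which its mean was above the filter. Gpm6a and Lrrn4 failed without SMGA/EGFP 2 (adjusted p = 0.0558 and 0.0933). Muc16 failed without SMGA/EGFP 1 or 3 or wild type 3, 4 or 6 (0.0514 to 0.200), Sowahb without SMGA/EGFP 2 or 3 or wild type 3, 4 or 6 (0.0519 to 0.146) and Nsfl1c without SMGA/EGFP 1 or 2 or wild type 3 or 6 (0.0519 to 0.219). Bnc1 failed without SMGA/EGFP 1, 2 or 3, SMAA/EYFP 1 or wild type 4 or 6 (0.0523 to 0.251), and Tcl1b3 passed in 2 of these fits, without wild type 1 or wild type 5 (0.0637 to 0.308 in the others). Tcl1b3 also failed in 6 of 13 other settings, at adjusted p = 0.106 with arrays centred on their median, 0.0543 without a filter, 0.0501 and 0.0514 with the 25th and 75th percentile filters, 0.0585 without a trend and 0.134 with only the arrays compared. With only the arrays compared, Nsfl1c (0.0920), Bnc1 (0.0764), Muc16 (0.0634) and Sowahb (0.0764) failed too, as did Nsfl1c (0.0655) and Bnc1 (0.0585) without a trend and Nsfl1c (0.0544) with arrays centred on their median. Msln passed without wild type 1 (-1.61, adjusted p = 0.0254). With the block, Muc16 (-1.63, adjusted p = 0.0554), Nsfl1c (adjusted p = 0.0700) and Sowahb (adjusted p = 0.142) did not pass.

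Several cell-type lists passed in SMGA/EGFP, with smaller medians than the mesothelium and with 0 members past the threshold over all genes. Urothelium, the epithelium that lines the bladder, was higher, with 26 of 27 genes above wild type, a median of 0.18 (adjusted p = 2.62e-05; adjusted p = 0.571 with an estimated correlation) and Foxq1 at 0.54 ± 0.19, Upk2 at 0.30 ± 0.14 and Upk1a at 0.28 ± 0.14. Endothelium was lower, with 17 of 18 genes below wild type, a median of -0.21 (adjusted p = 0.000621; 0.571 with an estimated correlation) and Icam2 at -0.94 ± 0.29, Sox18 at -0.45 ± 0.15 and Tek at -0.34 ± 0.11. Macrophages and other leukocytes were lower in 18 of 19 genes, with a median of -0.22 (adjusted p = 0.00122; 0.571 with an estimated correlation), Cx3cr1, a chemokine receptor, at -0.96 ± 0.37 and Lyz2, lysozyme, at -0.52 ± 0.20. Mast cell genes had a median of -0.39 over 3 genes (adjusted p = 0.0454; 0.544 with an estimated correlation), with 0 past over all genes and 2, the proteases Cpa3 (-0.43 ± 0.15) and Cma1 (-0.39 ± 0.16), adjusted over the list alone. In the first 3 of these lists SMGA/EGFP 1 ran the other way, with scores of -0.18 for urothelium, below 4 of 6 wild-type arrays, 0.19 for endothelium and 0.16 for leukocytes. Without it the list means were 0.31, -0.42 and -0.44, against 0.19, -0.25 and -0.27 with it, and without wild type 5 the urothelium mean was 0.12. Icam2 was at -0.54 without SMGA/EGFP 2, Sox18 at -0.22 without SMGA/EGFP 1, Lyz2 at -0.28 without SMGA/EGFP 3, Cpa3 at -0.24 without SMGA/EGFP 2 and Upk1a at 0.18 and 0.44 without SMGA/EGFP 2 and 1. Without SMGA/EGFP 2 the endothelium mean was -0.06 (adjusted p = 0.669), and without SMGA/EGFP 3 the leukocyte mean was -0.15 (adjusted p = 0.342). The mast cell call was lost without SMGA/EGFP 2 or 3, SMAA/EYFP 2, or wild type 1, 2 or 4, at adjusted p up to 0.266, and also as deposited (0.100), without a filter (0.0950) and within the first run (-0.26, adjusted p = 0.0579). Within that run the leukocyte call was lost too (-0.17, adjusted p = 0.0579).

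Neurons and Schwann cells had 11 of 12 genes higher in SMGA/EGFP than in wild type, with a median of 1.08 (adjusted p = 0.000442, and adjusted p = 0.571 with an estimated correlation). Prph, a neuronal intermediate filament, was at 1.57 ± 0.91, Chrna3, a nicotinic receptor subunit of ganglia, at 1.18 ± 0.59, and Erbb3, the neuregulin receptor of Schwann cells, at 0.37 ± 0.18. This difference depended on the runs of record numbers. The list score of wild type was 0.59 ± 0.83 (SD, n = 3) in the first run and -1.10 ± 0.36 in the second. Not every array followed its run: wild type 3 in the first was at -0.33 and SMAA/EYFP 3 in the second at 0.86. Within the first run the list's mean difference was 0.08 (camera adjusted p = 0.582, and 0.645 with the run as a block). Without SMGA/EGFP 2 the call was lost (0.68, adjusted p = 0.0586). Mesothelium scores of wild type also differed between the runs, at -0.08 and 0.60.

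Among lists of cell state, cell cycle genes were lower in SMGA/EGFP in 27 of 28 cases, with a median of -0.23 (adjusted p = 0.000233; adjusted p = 0.571 with an estimated correlation), Tpx2, a spindle assembly factor, at -0.51 ± 0.21, Ccne1 (cyclin E1) at -0.37 ± 0.14 and Racgap1 at -0.34 ± 0.14. Cytosolic heat shock genes were lower in 10 of 12 cases, with a median of -0.12 (adjusted p = 0.0183; 0.544 with an estimated correlation), Dnajb1 at -0.39 ± 0.14 and Hspa1b at -0.36 ± 0.12. Glucocorticoid and fasting response genes were higher in 11 of 15, with a median of 0.33 (adjusted p = 0.0212; 0.571 with an estimated correlation), Sgk1, a kinase induced by glucocorticoids, at 0.75 ± 0.26 and Cdkn1a at 0.49 ± 0.18. Angptl4, an inhibitor of lipoprotein lipase induced by fasting, ran against the list at -1.30 ± 0.29 and was its single member past adjusted over the list alone, with 0 over all genes; without SMGA/EGFP 3 it passed over all genes (-1.68, adjusted p = 0.0452), as did Tpx2 (-0.89, adjusted p = 0.0404). Smooth muscle receptors and ion channels were lower in 11 of 13 genes, with a median of -0.25 (adjusted p = 0.0482; 0.572 with an estimated correlation), Ednrb, an endothelin receptor, at -0.29 ± 0.11 and P2rx1, an ATP-gated channel, at -0.33 ± 0.20 (-0.09 without SMGA/EGFP 2 and -0.62 without SMGA/EGFP 1). The cell cycle score of SMGA/EGFP 3, 0.26, lay above every wild-type array, and without it the list's mean was -0.46, against -0.23, and the glucocorticoid mean 0.45, against 0.24. Without SMGA/EGFP 1, Ccne1 was at -0.22 and Sgk1 at 0.41, without SMGA/EGFP 2 Tpx2 was at -0.28, and without SMGA/EGFP 3 Racgap1 was at -0.56. Without SMGA/EGFP 1 the cell cycle mean was -0.06 (adjusted p = 0.645) and the glucocorticoid mean 0.01 (adjusted p = 0.783), and both calls were also lost without SMGA/EGFP 2 (adjusted p = 0.0654 for each). Heat shock lost its call without SMGA/EGFP 1 or 3 or wild type 2 (adjusted p = 0.0504 to 0.0853). Receptors and channels lost it without SMGA/EGFP 2 or 3, SMAA/EYFP 2, or wild type 1 or 5 (adjusted p up to 0.860), and had a mean of -0.07 with the run as a block (adjusted p = 0.606; 0.404 within the first run). It was also lost as deposited (0.0542) and with arrays centred on their median (0.0502).

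In total 10 lists passed, with 5 without SMGA/EGFP 2 and 6 within the first run of record numbers. The other 14 lists did not pass in SMGA/EGFP against wild type, at adjusted p = 0.0923 to 0.933. Circadian clock genes passed with the run as a block (mean 0.20, adjusted p = 0.0404) but not within the first run (0.0579). The medians of these lists were 0.16 for circadian clock, where Per1 at 0.84 ± 0.23 (0.49 without SMGA/EGFP 1) passed adjusted over the list alone, -0.09 for interferon response, 0.17 for immediate early genes, -0.42 for erythroid cells and -0.04 for oxidative phosphorylation, where Ndufs1 at -0.27 ± 0.07 passed adjusted over the list alone. Medians were -0.04 for fibroblasts and extracellular matrix, 0.01 for cytosolic ribosomal proteins, 0.02 for hypoxia and glycolysis, -0.03 for pericytes and -0.05 for adipocytes. Skeletal muscle, endoplasmic reticulum stress and Hedgehog, Wnt and BMP signalling had medians of -0.01, -0.01 and -0.04 and means of 0.57, 0.04 and 0.02, so median and mean differed in sign. The prostate and Wolffian duct list could not be tested.

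**Figure D3:**
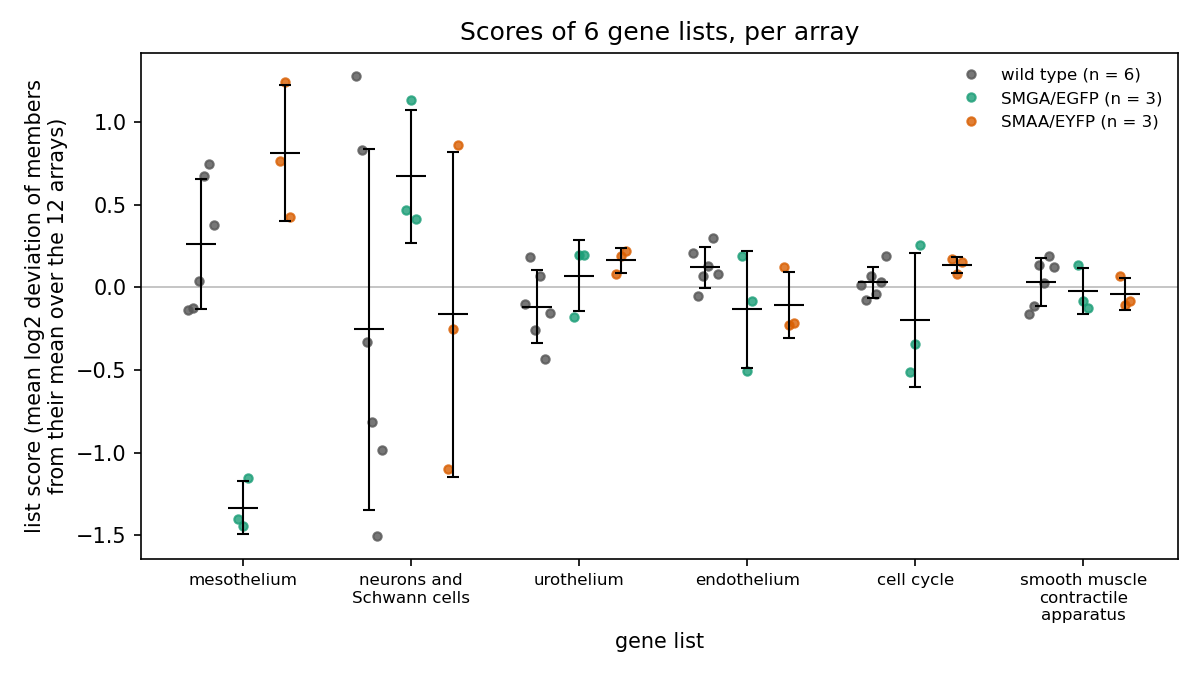
Score of 6 gene lists (mean log2 deviation of the members from their means over the 12 arrays) in each array (dots) of wild type (n = 6), SMGA/EGFP (n = 3) and SMAA/EYFP (n = 3), with the group mean and SD as bars. Mesothelium scores of the SMGA/EGFP arrays, -1.45 to -1.15, lie below every other array, whereas wild-type scores of neurons and Schwann cells spread from -1.50 to 1.28.

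SMAA/EYFP against wild type asked the same of the Acta2-driven transgene, and no single gene changed past the threshold. The smallest p belonged to Ldhb, the lactate dehydrogenase subunit of oxidative tissues, at 0.87 ± 0.12 (SE, n = 3 and 6; limma adjusted p = 0.125). The gene's 4 probe sets lay between 0.68 and 1.01. Lhfpl2, a tetraspan membrane protein, was at -0.72 ± 0.11 and Cdkn1b, the cyclin-dependent kinase inhibitor p27, at 1.35 ± 0.21 (adjusted p = 0.138 for each); a further Cdkn1b probe set was at 0.11. Ldhb and Cdkn1b passed with arrays centred on their median (adjusted p = 0.0109 and 0.0462) and with array weights (adjusted p = 0.00587 and 0.0197). Next came Ccdc91 at 0.79 ± 0.16 and Slc39a8, a zinc transporter, at 0.68 ± 0.14 (adjusted p = 0.565 for each), and Paqr5, a membrane progestin receptor, at 0.64 ± 0.14. Upk3b was at 0.48 ± 0.10, Tmem198b at -0.60 and Srsf5, a splicing factor, at -0.35 (adjusted p = 0.761), and Gpr160 at 0.56 (adjusted p = 0.874). Other probe sets above the filter were at 0.17 for Tmem198b, 0.26, -0.08 and 0.46 for Paqr5, and 0.33 and 0.36 for Ccdc91. For Lhfpl2 they were at -0.49 and -0.34, and for Upk3b at 0.51. Limma called 0 probe sets, with 1082 at an unadjusted p under 0.05, against 1125.9 by chance; the count was 5, all higher, with arrays centred on their median, and 5 with array weights.

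At the level of lists, urothelium was higher in SMAA/EYFP in 27 of 27 genes, with a median of 0.24 (camera adjusted p = 8.28e-10, and adjusted p = 0.533 with an estimated correlation). Snx31, a sorting nexin of the uroplakin route, was at 0.56 ± 0.16, Psca, a surface antigen, at 0.51 ± 0.17, Upk2 at 0.45 ± 0.14 and Krt7, a keratin, at 0.35 ± 0.11. Endothelium was lower in 17 of 18 genes, with a median of -0.24 (adjusted p = 1.90e-05; adjusted p = 0.533 with an estimated correlation), Eng at -0.46 ± 0.19, Kdr, a receptor of vascular endothelial growth factor, at -0.32 ± 0.16 and Cdh5, the cadherin of endothelial junctions, at -0.30 ± 0.15. Fibroblasts and extracellular matrix were lower in 25 of 27 genes, with a median of -0.13 (adjusted p = 0.000562; adjusted p = 0.576 with an estimated correlation), Pdgfra at -0.32 ± 0.11 and the collagens Col12a1 and Col5a1 at -0.21 ± 0.10 and -0.16 ± 0.08. Without SMAA/EYFP 1 the endothelium mean was -0.34, against -0.23, and Col12a1 was at -0.12, without SMAA/EYFP 2 Col12a1 was at -0.33, and without SMAA/EYFP 3 Cdh5 was at -0.17. In these 3 lists 0 members passed, over all genes or adjusted over the list alone, and the scores of the arrays overlapped with wild type. For urothelium SMAA/EYFP 1 was at 0.08, below wild type 2 at 0.18. For endothelium SMAA/EYFP 1 was at 0.12, above wild type 3 at 0.07, and for fibroblasts at -0.10, above wild type 2 at -0.13.

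Mesothelium was higher in SMAA/EYFP in 5 of 6 genes, with a median of 0.62 (adjusted p = 0.000539; adjusted p = 0.533 with an estimated correlation), Msln at 0.94 ± 0.30, Gpm6a at 0.72 ± 0.34 and Muc16 at 0.67 ± 0.30. Over all genes 0 passed, and 2 (Upk3b and Msln) passed adjusted over the list alone. Upk3b is also a uroplakin, so its rise cannot be assigned to mesothelium or urothelium. Against the wild-type arrays of the second run alone, the list's mean was 0.21 (adjusted p = 0.0867), as it was with the run as a block (0.21, adjusted p = 0.0666), in place of 0.55. Without SMAA/EYFP 2 it was 0.33 (adjusted p = 0.0687), with Gpm6a at 0.40. The other 20 lists did not pass, at adjusted p = 0.0592 to 0.928 and medians of -0.57 to 0.18; in mast cells, circadian clock and glucocorticoid response the median (0.03, 0.01 and -0.05) and the direction of the test differed. The number of lists past the threshold was 4, with 9 without wild type 1 or 2 or with the run as a block, 12 without SMAA/EYFP 1 and 7 within the second run. With the block, at the preset correlation, 6 further lists passed. Neurons and Schwann cells had a mean of 0.94 (adjusted p = 7.72e-07; 0.89 and 1.53e-05 within the second run), against 0.09 without the block. The result for this list therefore depended on which wild-type arrays were used, and whether the run hides or makes a difference is not known. The others were the contractile apparatus, receptors and ion channels (-0.22, adjusted p = 0.00947), leukocytes (-0.26, 0.00108), immediate early genes (0.30, 0.0250) and oxidative phosphorylation (-0.07, 0.0319). Immediate early genes (0.0713) and oxidative phosphorylation (0.0981) did not pass within the second run.

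SMGA/EGFP against SMAA/EYFP tested directly whether the transgenic groups differed, and mesothelial genes were among those that did. Each transgenic group lies in its own run of record numbers, so the run also enters this comparison. Gpm6a was lower in SMGA/EGFP by a log2 difference of -3.46 ± 0.39 (SE, n = 3 and 3), Lrrn4 of -3.32 ± 0.42, Muc16 of -2.74 ± 0.35 and Msln of -2.35 ± 0.35 (limma adjusted p = 0.0178 for Msln and smaller for the others). The mesothelium list was lower in 6 of 6 genes with a median of -2.54 (camera adjusted p = 1.98e-11, adjusted p = 0.0880 with an estimated correlation, 0.00140 with fry). Over all genes 4 members passed, against 5 adjusted over the list alone. The fifth was Upk3b at -0.61 ± 0.12, which passed over all genes without wild type 4 (limma adjusted p = 0.0341). As a uroplakin, Upk3b cannot be assigned to mesothelium or urothelium here either. With the run as a block the list's mean was -1.47 (adjusted p = 1.46e-10), against -2.14 without it, but none of these 4 genes passed: Gpm6a was at -2.52 (adjusted p = 0.196), Lrrn4 at -2.35 (0.440), Muc16 at -1.86 (0.412) and Msln at -1.64 (1.00). Cell cycle genes were lower in 28 of 28 cases, with a median of -0.27 (adjusted p = 4.79e-05; adjusted p = 0.822 with an estimated correlation, and 0.0537 at the preset one without SMGA/EGFP 2). Cdc6, a replication licensing factor, at -1.24 ± 0.32 was the 1 member past adjusted over the list alone, with 0 over all genes, and the helicase subunits Mcm3 and Mcm5 were at -0.66 ± 0.23 and -0.57 ± 0.23. This came from SMGA/EGFP 1 and 2, since the score of SMGA/EGFP 3, 0.26, lay above every SMAA/EYFP array (0.08 to 0.17). Without SMGA/EGFP 3 the list's mean was -0.56, and without SMGA/EGFP 1 it was -0.17, against -0.34, with Cdc6 at -0.74, Mcm3 at -0.33 and Mcm5 at -0.23.

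Further genes lower in SMGA/EGFP than in SMAA/EYFP were Bst1 (-4.03 ± 0.40, from near background in SMGA/EGFP and so an uncertain fold, -4.49 to -2.99 over the settings), Bnc1 (-3.22 ± 0.41), Fgfbp1 (-3.11 ± 0.26), Smpd3 (-1.89 ± 0.21), Atp6ap2 (-1.27 ± 0.09, adjusted p = 6.05e-05) and Nsfl1c (-1.18 ± 0.15). To these came Dmkn, a secreted protein of epithelia, at -2.09, Dpp4, a surface peptidase, at -2.07 (adjusted p = 0.0169), Slc39a8 at -1.04 and Atp10d, a phospholipid flippase, at -0.81. For Atp6ap2 the difference was in 1 probe set, and the gene's other probe sets were at -0.00097 and 0.0017. Arid5b, a DNA-binding protein, was higher at 1.19 (adjusted p = 0.0375), as was Tcl1b3 at 1.13 (adjusted p = 0.0285); neither passed with arrays centred on their median (adjusted p = 0.0709 for each), a setting that moved the median of all differences by -0.10. In total 18 probe sets passed, 2 higher and 16 lower, for 16 genes, and 2097 had an unadjusted p under 0.05. The count was 9 without SMGA/EGFP 2 and 4 without SMAA/EYFP 2. Without SMAA/EYFP 2, Bnc1, Lrrn4, Muc16 and Nsfl1c failed (adjusted p = 0.0520 for each), Nsfl1c also without SMGA/EGFP 2 (0.0510). Msln and Dpp4 failed without SMGA/EGFP 1 or 2 or SMAA/EYFP 1 or 2 (0.0551 to 0.146 and 0.0752 to 0.143), Slc39a8 without SMGA/EGFP 2 or 3 or SMAA/EYFP 2 or 3 (0.0526 to 0.107) and Dmkn without SMGA/EGFP 2 or 3 or any SMAA/EYFP array (0.0597 to 0.166). Atp10d failed without any SMGA/EGFP array, SMAA/EYFP 2 or 3 or wild type 3, 5 or 6 (up to 0.213), Tcl1b3 without any transgenic array or wild type 3 or 6 (up to 0.192), and Arid5b without SMGA/EGFP 1 or 2, SMAA/EYFP 1 or 2 or wild type 1, 2, 5 or 6 (up to 0.246). With only the arrays compared, Dpp4 (0.0751), Slc39a8 (0.0903), Atp10d (0.114) and Arid5b (0.0926) failed. Without a trend, Msln (0.0520), Dmkn (0.0634), Atp10d (0.0609), Tcl1b3 (0.0520) and Arid5b (0.0733) failed, and with array weights Dpp4 (0.0719) and Arid5b (0.108). With the run as a block it was 2, Atp6ap2 (-1.34, adjusted p = 0.00463) and Fgfbp1 (-2.53, adjusted p = 0.0140). Among the genes that then failed, Bnc1 was at -1.94 (adjusted p = 0.168), Bst1 at -3.32 (0.153), Dmkn at -1.32, Dpp4 at -1.77 and Arid5b at 0.99 (1.00 for each of these 3).

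The other 22 lists did not differ past the threshold between the transgenic groups, at adjusted p = 0.149 to 0.967 and medians of -0.46 to 1.17. Tgfb2, a growth factor of the Hedgehog, Wnt and BMP list, was at 0.85 ± 0.18 and passed adjusted over the list alone, with 0 over all genes, as did the mast cell proteases Cma1 (-0.56 ± 0.19) and Cpa3 (-0.46 ± 0.18, or -0.27 without SMGA/EGFP 2). In 5 of these lists (endothelium, adipocytes, immediate early genes, oxidative phosphorylation, and Hedgehog, Wnt and BMP signalling) median, mean and test differed in sign. With the run as a block, neurons and Schwann cells changed sign, from 0.83 to -0.86 (adjusted p = 0.000886), and the contractile apparatus (0.18, 0.000886), urothelium (-0.20, 0.00208) and fibroblasts and extracellular matrix (0.18, 0.00364) passed as well. The number of lists past the threshold was 2, with 6 with the run as a block, 5 without SMGA/EGFP 3, and 4 without SMGA/EGFP 1, SMAA/EYFP 1 or SMAA/EYFP 3.

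Both transgenic groups against wild type asked for a change common to transgenic animals, and 1 gene passed. The single Atp6ap2 probe set fell by 0.70 ± 0.07 (SE, n = 6 and 6; adjusted p = 0.00141), but its level in SMAA/EYFP, 14.50 ± 0.04 (SD), was close to that in wild type, 14.56 ± 0.12, and in SMGA/EGFP it was 13.23 ± 0.16. With arrays centred on their median it did not pass (adjusted p = 0.0981). Lhfpl2 at -0.55 and Pnisr at -0.51 (adjusted p = 0.204 for each), Sowahb at 0.82 (adjusted p = 0.370) and Ldhb at 0.52 did not pass. Pnisr and Sowahb passed with array weights (adjusted p = 0.0301 for each). Not passing were also Rbm47 at 0.75, Sdc4, a heparan sulphate proteoglycan, at 0.43, Fgfbp1 at -0.87, Bst1 at -1.29 and Fam13b at -0.26. Fgfbp1 and Bst1 averaged opposite directions. Their levels were 11.46 and 8.69 in wild type, 9.03 and 5.38 in SMGA/EGFP, and 12.15 and 9.41 in SMAA/EYFP. Rbm47 was at 8.57 in wild type, 9.76 in SMGA/EGFP and 8.89 in SMAA/EYFP, and a brighter probe set of the gene differed by 0.15. In all, 941 probe sets had an unadjusted p under 0.05.

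Of the lists, urothelium was higher in both groups taken as one in 27 of 27 genes, with a median of 0.22 (adjusted p = 6.02e-12; adjusted p = 0.453 with an estimated correlation) and Snx31 at 0.43 ± 0.13, Upk2 at 0.37 ± 0.12 and Upk1a at 0.34 ± 0.11. Endothelium was lower in 17 of 18 genes, with a median of -0.24 (adjusted p = 2.59e-07; 0.453 with an estimated correlation) and Icam2 at -0.71 ± 0.23 and Tek at -0.26 ± 0.09. Leukocytes were lower in 16 of 19 genes (median -0.16, adjusted p = 0.000586; adjusted p = 0.453 with an estimated correlation), with Coro1a at -0.40 ± 0.11 and Ptprc at -0.39 ± 0.12. Neurons and Schwann cells were higher in 12 of 12 (median 0.50, adjusted p = 0.00127; 0.508 with an estimated correlation), with Uchl1 at 0.37 ± 0.16 and Mbp at 0.35 ± 0.15. Mesothelium was lower in 5 of 6 (median -0.49, adjusted p = 0.00594; 0.453 with an estimated correlation), with 0 past over all genes and 3, Lrrn4, Gpm6a and Muc16, adjusted over the list alone. This averages opposite directions, since the list's mean was -1.59 in SMGA/EGFP and 0.55 in SMAA/EYFP. Fibroblasts and extracellular matrix (median -0.11, adjusted p = 0.00730), smooth muscle receptors and ion channels (-0.21, adjusted p = 0.0238) and oxidative phosphorylation (-0.03, adjusted p = 0.0456) were lower, at adjusted p = 0.510, 0.508 and 0.549 with an estimated correlation. Of the 8 lists, 5 passed without wild type 5. The neuron mean of 0.51 was 0.25 without SMAA/EYFP 3 and 0.82 without wild type 1, and the endothelium mean of -0.24 was -0.15 without SMGA/EGFP 2. Leaving out 1 array ended the oxidative phosphorylation call without SMGA/EGFP 1 or 2, SMAA/EYFP 2 or 3 or wild type 2, 3, 4 or 5 (adjusted p = 0.0534 to 0.122), as did values as deposited (0.0554), centring on the median (0.0970), the run as a block (0.0612) and no filter (0.0678). Leaving out 1 array also ended the receptor call without SMGA/EGFP 2, SMAA/EYFP 3 or wild type 5 (0.0697 to 0.244), the fibroblast call without SMGA/EGFP 3 or wild type 5 (adjusted p = 0.0852 and 0.0584) and the leukocyte call without SMGA/EGFP 3 (adjusted p = 0.0517). The other 16 lists did not pass, at adjusted p = 0.0534 to 0.958, and in 4 of them (skeletal muscle, endoplasmic reticulum stress, cytosolic ribosomal proteins, hypoxia and glycolysis) median and mean differed in sign.

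Across the 22518 probe sets, the differences of SMGA/EGFP and SMAA/EYFP from wild type correlated with r = 0.0384. In 100 simulations of unchanged groups that shared the same wild-type arrays, r was 0.333 on average and at most 0.360. The covariance was 0.00200 against 0.0138 simulated, a difference of -0.0118. These simulations held no difference between the runs of record numbers, which the transgenic groups do not share, so they do not show whether an effect was shared. When each transgenic group was set against another 3 of the wild-type arrays, r ran from -0.512 to 0.139 over 20 splits and was above 0 in 3. It was 0.0733 with each group against the wild-type arrays of its own run and -0.512 with the runs crossed. At an unadjusted p under 0.05, 50 probe sets were higher in both comparisons, where independent lists give 16.6, and 45 were lower in both, where they give 19.99, and the shared wild-type arrays make these lists dependent.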

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

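The tests of ganglia, of a change in cis at a single chromosomal site, of chance placement and of an inherited segment on chromosome 6, and of a mixture, a label exchange or another tissue for wild type 4 were chosen only after the result was seen.

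In 62 single values and list scores of the 6 wild-type arrays, 8 had an array far from the others (gap over range above Dixon's 95% critical value), where about 1 in 20, or 3.1, is the number chance gives. In wild type 4 these were Eif2s3y (0.939), Kdm5d (0.902), Uty (0.895) and Xist (0.902). In wild type 2 they were the skeletal muscle list score (0.682), the Actb ratio (0.674) and Sowahb (0.664), and in wild type 5 Dpp4 (0.687).

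Differences between the transgenic groups, each tested directly with limma, drew attention to 18 probe sets. The log2 differences were -1.27 for Atp6ap2, -3.11 for Fgfbp1, -4.03 for Bst1, -1.89 for Smpd3, -3.46 for Gpm6a, -2.74 for Muc16, -3.22 for Bnc1, -3.32 for Lrrn4, -1.18 for Nsfl1c, -2.07 for Dpp4, -2.35 for Msln, -1.04 for Slc39a8, -2.09 for Dmkn, -0.81 for Atp10d, 1.13 for Tcl1b3 and 1.19 for Arid5b. The list means were -2.14 for mesothelium and -0.34 for cell cycle.

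Other splits of the same arrays were tested for each comparison. For SMGA/EGFP against wild type, 4 of 84 splits gave as many probe sets as the real 14, a share under 0.05 that argues against chance only if the runs of record numbers are disregarded, and 1 probe set passed within the first run. The highest other split gave 136 (SMGA/EGFP 3 with wild type 1 and 2), several times the real count, which points to a structure of the samples. For its lists chance cannot be excluded (17 of 84 splits, real 10, highest other 13). For SMAA/EYFP against wild type the real count of 0 probe sets is reached by 84 of 84 splits whatever the data, so this count decides nothing. Its highest other split gave 300 (wild type 1 and 2 with SMAA/EYFP 3), again a structure of the samples. For its lists chance cannot be excluded (48 of 84, real 4, highest other 10). The 10 splits between the transgenic groups are too few for a share under 0.05 (probe sets 1 of 10, real 18, highest other 0; lists 9 of 10, real 2, highest other 15). For both groups against wild type chance cannot be excluded for probe sets (9 of 100, real 1, highest other 33) or lists (28 of 100, real 8, highest other 14). The split of all 12 arrays by the runs of record numbers gave 52 probe sets and 4 lists, more probe sets than the real 1, which stayed at adjusted p = 0.00282 with the run as a block.

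Mesothelial genes were lower in SMGA/EGFP. The genes that fell lie on 7 chromosomes of assembly GRCm38.p6. This argues against a change in cis at a single chromosomal site as the reason for all of them. It cannot exclude such a change for genes that share a chromosome, since the count took no account of distance. Fgfbp1 and Bst1 lie on chromosome 5, Gpm6a and Smpd3 on chromosome 8, and Lrrn4 and Nsfl1c on chromosome 2. For a loss of outer tissue with its ganglia, the neurons and Schwann cells list was at 0.93 ± 0.50 (SE) where mesothelium was at -1.59 ± 0.19 (gap 2.52 ± 0.67). That neuron difference depended on the runs of record numbers. Within the first run it was 0.08 ± 0.53 (gap 1.34 ± 0.62, 3 arrays against 3), too imprecise to decide on a loss with ganglia. Fewer mesothelial cells in these samples may be the reason, but a second mesothelial list, with 6 of 8 genes tested, had a median of -0.12 with 5 lower and 1 higher (exact permutation test of its score, two-sided, p = 0.25), with Nkain4 at -0.44 ± 0.16 (SE), Ildr2 at -0.28 ± 0.28, Anxa8 at -0.21 ± 0.24, Efemp1 at -0.03, Ptgis at -0.02 and Aldh1a2 at 0.03. Other cells that express Efemp1 and Ptgis would hide a loss there, so this cannot be told apart from lower expression in the same cells. A change at 1 site that acts in trans, dissection, litter and an effect of the transgene stay open, untested.

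Genes with an unadjusted p under 0.05 in SMAA/EYFP against wild type lay close together on chromosome 6, where a window of 25 genes from Borcs5 to Aebp2, which holds Cdkn1b, had 9 of them (6 higher, 3 lower). By chance an average window holds 1.44, but this window was picked as the fullest, and the fullest window of permuted gene orders held a median of 7. A single SMAA/EYFP array is argued against, since the fullest window stayed on this part of chromosome 6 without each of the 3, although it moved to chromosome 15 without wild type 2 or wild type 4. Chance placement stays open, with a window as full in 19 of 1000 permuted gene orders (highest 10; one-sided permutation p = 0.0799 adjusted over 4 comparisons), as does chance among the arrays (14 of 84 splits, highest other 11). Among the 10 genes of smallest p named for this comparison, Ldhb (0.87) and Ccdc91 (0.79) also lie on chromosome 6, outside this window. Apart from Cdkn1b, the others lie on other chromosomes. A segment inherited with the transgene could also explain the window. Its score lay above every wild-type array in 3 of 3 SMAA/EYFP arrays, but the genes were chosen from the same arrays, so this cannot be told. Whether Ldhb and Ccdc91 belong to such a segment was not tested.

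Wild type 4 expressed Xist and lacked Y-linked transcripts. Tissue of both sexes in 1 sample is argued against by Eif2s3y at 0.704% of the median of the others. Another tissue is argued against by a mean correlation of 0.972 with the other wild-type arrays, within their 0.967 to 0.976. All 12 labels are male and 0 other arrays had that pattern. An exchange of labels among the 12 arrays would therefore not explain a female array, and these genes cannot test whether such an exchange occurred. A female animal under a male label is the likely reason: 4 X-linked genes that escape silencing were on average 0.32 higher than in the other 11 arrays (SD 0.07), with Eif2s3x at 0.45, Kdm5c at 0.36 and Kdm6a at 0.50 above all 11, and Ddx3x at -0.02. Whether the label or the sample was exchanged outside this series stays open.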

How the results depend on the processing

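Fits within 1 run of record numbers were chosen only after the result was seen. With 3 to 6 arrays per group and 8.33% to 10.5% of values below the pseudocount, weak genes and small differences are the least certain, and "only the arrays of the groups compared" equals the fit to all 12 arrays for both groups against wild type, so it was not run there.

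Counts of probe sets, 14, 0, 18 and 1 in SMGA/EGFP against wild type, SMAA/EYFP against wild type, SMGA/EGFP against SMAA/EYFP and both against wild type, moved with some settings. The 75th percentile filter gave 5 and 10 in SMGA/EGFP against wild type and against SMAA/EYFP (fewer probe sets tested), and only the arrays compared gave 8 in SMGA/EGFP against wild type (fewer arrays). Centring on the median gave 5 in SMAA/EYFP and 0 in both groups, and array weights 5 and 3, for causes that were not tested. With 1 probe set per gene, both groups gave 0. The probe set of highest mean then stands for a gene, and for Atp6ap2 that was not the one that passed but another, at -0.03. The run as a block gave 2 between the transgenic groups, and the first run alone gave 1 in SMGA/EGFP (fewer arrays). Leaving out 1 array gave 6 to 20, 0 to 0, 4 to 22 and 1 to 1.

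Numbers of lists, 10, 4, 2 and 8, became 0 in each comparison with an estimated correlation, since members move together, and 1, 0, 1 and 0 with fry. The block gave 9 in SMAA/EYFP and 6 between the transgenic groups, the first run alone 6 and the second run alone 7. Leaving out 1 array gave 5 to 11, 4 to 12, 2 to 5 and 5 to 10. The mesothelium mean kept its value and lost its call with an estimated correlation, at -1.59 (adjusted p = 0.143), 0.55 (0.533), -2.14 (0.0880) and -0.52 (0.453), and with fry at 0.55 (0.449) and -0.52 (0.295). In SMAA/EYFP it was 0.21 with the block (0.0666) and 0.21 in the second run (0.0867), and 0.33 to 0.74 with 1 array left out.

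Promoter genes, all within 0.03 of 0 at their main probe sets, changed sign without passing. Centring moved the median of all differences by -0.06 in SMGA/EGFP and 0.03 in SMAA/EYFP against wild type and by -0.10 between the transgenic groups. Each shift was larger than these genes' differences in that comparison. The cause in the other settings was not tested. Acta2 was at 0.0039, 0.0016 and 0.0028 as deposited in SMGA/EGFP, SMAA/EYFP and both against wild type, at 0.041 (SMAA/EYFP) and -0.12 (SMGA/EGFP against SMAA/EYFP) when centred, and at 0.034, -0.066 and 0.0011 (both) with array weights. Actg2 was at -0.052 (SMGA/EGFP) and -0.12 (SMGA/EGFP against SMAA/EYFP) when centred, at -0.0090, -0.014 and -0.0020 (both) with array weights, and in SMAA/EYFP at -0.011 with the block and -0.012 in the second run. Leaving out 1 array gave Acta2 -0.040 to 0.0044, -0.081 to 0.022, -0.042 to 0.062 and -0.050 to 0.0014, and Actg2 -0.0026 to 0.024, -0.0081 to 0.015, -0.0065 to 0.023 and -0.00098 to 0.014, in the order of the comparisons above. Upk3b in SMGA/EGFP was at 0.011 with the block and 0.011 in the first run. The correlation of effects was -0.15 as the median of 20 splits of the wild-type arrays, most of which mix the runs, and 0.073 with each group against the wild-type arrays of its own run.

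Over the settings that left no array out for this purpose, 96 list means kept their direction and call and 62 lost the call. Of the named genes' values, 1465 kept both, 53 lost the call, 6 gained it and 2 reversed. Values that kept both include genes that passed neither before nor after, so this number does not measure how stable the calls were. With each array left out in turn, 251 list means kept both and 37 lost the call. Of the named genes' values, 1325 then kept both, again with genes that never passed, 78 lost the call and 4 gained it.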
